A study of Drosophila melanogaster with 150 samples.

How the data were processed

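Whole-body RNA of adult male Drosophila melanogaster was measured on 150 Affymetrix arrays. The flies came from 75 recombinant inbred lines, called roo lines, and each line has an array labelled as control and an array labelled as lead. Per the labels, control food held 250 uM sodium acetate and lead food held 250 uM lead acetate. In each vial 20 males and 20 females laid on 10 ml of food for 3 days at 25 degrees C, and 65 male progeny aged 5 to 10 days were pooled and frozen. RNA was extracted from 50 mg of flies per the labels' protocols. Each array is therefore a pool of males from a vial, with a single array per line and diet.

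The deposited table holds values on a log2 scale, inferred from their range of 1.93 to 14.04 and from the near-identical distributions of the arrays. The base of the logarithm, the summarisation and the normalization software are not given in the sources used here, so a difference is a log2 difference only under that reading. The lowest array median was 5.29 and the highest was 5.55, a span of 0.26. A rule set beforehand asked for further normalization only above a span of 0.5, so the deposited values were used without change. There were 0 missing values and 0 identical pairs of arrays. For arrays, their number limits the precision.

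The table holds 18952 probe sets, of which 183 array controls were left out and 18769 were tested with no filter on signal. The platform table given for this work lists 14049 of the tested probe sets. Exactly 1 gene symbol was given for 13646 probe sets, several for 402 and none for 4721, and only those with 1 symbol are named. Names were compared with a gene table of the assembly Release 6 plus ISO1 MT, in which 13543 matched and 0 symbols needed updating. The build behind the array design is not given in the sources used here, so no coordinates are printed and that table was used for names and for the order of genes.

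Diet differences were tested with limma 3.58.1 in R 4.3.3 on lead minus control within lines, which is the fit with line as a block. The pairing comes from the labels, which name the same inbred line on both diets. As a check, deviations from the diet means correlated with a mean r of 0.0668 between the arrays of a labelled line, against 0.000471 between lines. Own-line values ran from -0.355 to 0.640, and the highest value between lines was 0.783. Of 75 lines 34 exceeded 0.1, but the share between lines was not computed, so that count does not support the pairing. Calls used a Benjamini-Hochberg adjusted p under 0.05. The line effect was limma's moderated F-test of the line terms beside diet, with the Pearson correlation of control and lead values over the 75 lines as its size. The spread between lines was compared by the Pitman-Morgan test, which correlates sum and difference over lines. The titles number 57 lines from 1 to 100 and 18 lines above 200, and what these series mean is not given, so they were compared as a check of structure, in level and in response. P-values measure the spread between these lines.

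A total of 22 gene lists were fixed: metal transport and metallothioneins, iron handling, heme synthesis and breakdown, glutathione transferases and synthesis, cytochrome P450s, oxidative stress defence, heat shock, antimicrobial peptides and recognition, Turandot stress genes, neuronal and synaptic genes, phototransduction, circadian clock, female yolk and eggshell, male accessory gland and ejaculatory duct, testis, gut digestive enzymes, muscle, nutrient and insulin response, ribosomal proteins, mitochondrial respiratory chain, proteasome, and odorant binding proteins. Together they held 650 measured genes among 11981 symbols. Each gene was represented by its probe set of highest mean. Lists were tested with limma's camera and a correlation estimated per list, with fry beside it.

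The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named up to 10 genes per direction past the threshold for diet, or the 5 of smallest p per direction where fewer passed. It also named the metallothioneins MtnA to MtnD and the heme synthesis genes whatever their result, up to 12 genes with a line effect, and up to 6 genes per direction for the spread. Up to 4 members were to be named in a list with members past the threshold, and up to 5 genes per direction for the line number series.

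The alternatives were the fit without the block, a filter to probe sets above the median of mean signal, quantile normalization, median centring, array weights, a signed-rank test, thresholds of 0.01 and 0.1, a preset list correlation of 0.01, all probe sets of a gene, a rank form of the spread test, each line number series alone, and all lines but the 8 holding the arrays of lowest correlation with the rest. Surrogate variables were planned as covariates and are not reported, since their tool was not usable with these values. Permutation tests used 1e+05 resamples, and each result across probe sets was set against 100 regroupings of the arrays, the real one included. Intervals are at the 95% level. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

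The tests were tested on simulated data made from these arrays, with diet labels swapped at random within lines and known changes added to 200 probe sets. A diet shift of 0.25 was recovered in 88.5% of them and a shift of 0.1 in 28.5%, with 2 and 1 other calls among 18769. A correlation between diets of 0.5 was recovered in 93.0% after random pairing of lines, with 7 other calls, and one of 0.3 in 23.5%, with 8. A level difference of 0.5 between line number series was recovered in 97.5% and a response difference of that size in 86.0%, while differences of 0.25 were recovered in 78.0% and 32.5%. A list shift of 0.1 was recovered in 77.3% of 22 lists and a shift of 0.25 in 100%. For the spread, a log2 variance ratio of 1 was recovered in 35.5% and a ratio of 2 in 100% of the changed probe sets, but 331 unchanged probe sets were called too, so calls of that test are not held at the stated error rate.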

Results

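Expression was measured in adult males of 75 recombinant inbred lines of Drosophila melanogaster, each reared on control food and on food with lead acetate. The 150 arrays fall into 75 labelled control and 75 labelled lead, with a pair of arrays for every line. Median signal was between 5.29 and 5.55 on the log2 scale on every array. The median correlation of an array with the others had a median of 0.982 and was lowest at 0.954. No metallothionein passed between the labelled diets and the arrays of a labelled line were barely more alike than others, as given below, so groups are named throughout as the arrays labelled control and the arrays labelled lead. All differences are labelled lead minus labelled control.

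The first question was which genes responded to lead in the food. Metallothioneins are small cysteine-rich proteins that bind metals. MtnB, MtnC and MtnD differed strongly between arrays, MtnA less so, and none passed the threshold between the labelled diets. MtnB had a mean log2 signal of 9.58 ± 3.23 (SD, n = 75) on the arrays labelled control and 9.77 ± 3.38 (SD, n = 75) on those labelled lead. The difference was 0.20, with a 95% interval from -0.78 to 1.18 and an adjusted p of 1.00 in limma. MtnB had the largest SD of all 18769 probe sets, 3.30 over the 150 arrays, against a median SD of 0.219 for a probe set. No array lay between 8.99 and 11.02, a gap with 74 arrays below it and 76 above. Of the arrays labelled control, 39 lay below the gap and 36 above, and of those labelled lead, 35 lay below and 40 above. Fisher's exact test of side against labelled diet gave p = 0.624, 2-sided.

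Both arrays of a labelled line lay below the gap in MtnB in 22 lines and above it in 23. In 17 lines the control array was below and the lead array above, and in 13 lines the reverse held. MtnD differed between the labelled diets by 0.07 (interval -0.50 to 0.64), MtnC by -0.05 (-0.48 to 0.38) and MtnA by -0.08 (-0.22 to 0.07). None passed the threshold. MtnA was high on every array, between 12.03 and 14.04.

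**Figure D1:**
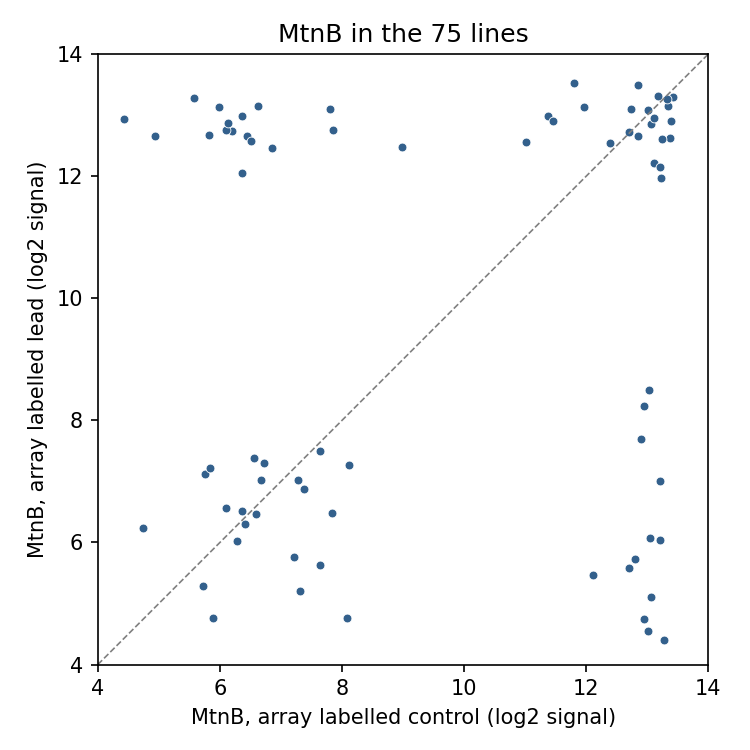
Each point is one of the 75 lines, with the log2 signal of MtnB on its array labelled control on the x axis and on its array labelled lead on the y axis; the dashed line marks equal signal. The lines fall into 4 clusters of 22, 23, 17 and 13, with no array between 8.99 and 11.02.

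Across all genes, 0 of 18769 probe sets passed between the labelled diets in limma with line as a block. At an unadjusted p under 0.05 there were 490 probe sets, 295 higher and 195 lower, where 938 are expected with no effect. The median standard error was 0.0344, and the whole 95% interval lay within 0.25 of 0 for 94.0% of probe sets and within 0.5 for 98.9%. These intervals hold for the labels as given. If values and labels do not belong together, a possibility raised below, they set no bound on an effect of lead. The genes of smallest p that were higher on the arrays labelled lead were Rpn8, a proteasome lid subunit, at 0.088 ± 0.023 (SE), Ku80, a DNA end-binding protein, at 0.13 ± 0.038, CG7668 at 0.14 ± 0.041, the gustatory receptor Gr93b at 0.073 ± 0.022 and the iron-sulfur assembly factor Nubp1 at 0.079 ± 0.024. Those that were lower were CG14441 at -0.12 ± 0.034, CG15282 at -0.15 ± 0.042, Hgsnat at -0.070 ± 0.023, CG12091 at -0.11 ± 0.035 and CG6688 at -0.10 ± 0.034. Each had an adjusted p of 1.00 after rounding. Rpn8 was higher on the lead array in 54 of 75 lines, at an unadjusted p of 0.000239. The difference of 3' and 5' probe sets of Act5C, a sign of RNA quality, was 2.74 ± 0.611 (SD) on the arrays labelled control and 2.73 ± 0.559 on those labelled lead, with a sign-flip permutation p of 0.952.

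Genes of heme synthesis, a pathway whose enzyme Pbgs is a known target of lead, were named in advance. Pbgs differed by 0.013 ± 0.072 (SE, 75 lines), Alas, the first enzyme of the pathway, by -0.027 ± 0.049, and FeCH, the last, by -0.0074 ± 0.037. Urod differed by -0.0093 ± 0.040, Uros1 by 0.034 ± 0.033, Uros2 by -0.013 ± 0.040, Coprox by 0.016 ± 0.026 and Ppox by 0.011 ± 0.030. None passed the threshold. The other probe sets of FeCH did not pass either.

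Of the 22 gene lists, 0 passed between the labelled diets by camera with an estimated correlation, and 0 by fry. The smallest camera adjusted p was 0.316 and the smallest fry adjusted p was 0.545, both for the proteasome. The 40 proteasome genes had a mean difference of 0.0319 ± 0.0153 (SE over lines), positive in 47 of 75 lines. Rpn8 was the single member past the threshold when adjusted over the list alone, at 0.00955, and in every other list the count adjusted over the list alone was 0. In all lists the count adjusted over all genes was 0.

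For lists related to metals and detoxification the mean difference was 0.000375 ± 0.0559 for 24 metal transport and metallothionein genes, whose median was -0.0061 and whose camera direction was down. It was -0.0219 ± 0.0237 for 13 iron handling genes and 0.0021 ± 0.0197 for 8 heme genes. It was 0.0064 ± 0.0427 for 35 glutathione transferase genes, -0.0186 ± 0.0383 for 81 cytochrome P450s and -0.0050 ± 0.0266 for 17 oxidative stress genes. Heat shock genes, 13 in number, differed by 0.0169 ± 0.0583, the 4 Turandot genes by 0.0632 ± 0.0922 and the 25 antimicrobial and recognition genes by -0.0413 ± 0.0511. Single lines moved several of these means. Cytochrome P450s differed by -0.0072 and glutathione transferase genes by 0.0209 without line 97. The sign turned for heat shock genes (-0.0062 without line 84) and for oxidative stress genes (0.0023 without line 46).

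For tissue and process lists the mean differences were 0.0012 ± 0.0335 for 43 neuronal genes, whose median was -0.0051, -0.0401 ± 0.0477 for 18 phototransduction genes, -0.0221 ± 0.0300 for 10 clock genes and -0.0642 ± 0.0811 for 22 muscle genes. They were -0.0822 ± 0.117 for 35 digestive enzymes, -0.0356 ± 0.0320 for 69 respiratory chain genes, -0.0111 ± 0.0161 for 41 ribosomal proteins and -0.0269 ± 0.0262 for 47 odorant binding proteins, whose median was 0.0031. Male accessory gland genes, 25 in number, differed by 0.0070 ± 0.0463, 35 testis genes by 0.0073 ± 0.0336, with a median of -0.0034, and 24 nutrient and insulin genes by 1.54e-05 ± 0.0378, with a median of -0.0171. The 21 female yolk and eggshell genes differed by 0.11 ± 0.13, and by 0.0437 ± 0.107 without line 213, whose array labelled lead was far above the others in these genes. Without line 38, whose array labelled control was also high, they differed by 0.170 ± 0.115, and without both lines by 0.0994 ± 0.0927, the lines having been chosen by these values. Digestive enzymes differed by -0.0414 without line 226 and muscle genes by -0.0400 without line 42. Phototransduction genes differed by -0.0196 without line 84 and clock genes by -0.0106 without line 13. The sign turned for neuronal genes (-0.0105 without line 226), testis genes (-0.0053 without line 84) and male accessory gland genes (-0.0074 without line 211). Each line was the one whose removal moved that list most. With the preset correlation of 0.01 camera called 5 lists, the proteasome and the yolk and eggshell list higher and the respiratory chain, digestive enzymes and muscle lower, while swapping the diet labels within lines gave as many in 84 of 100 splits, with a median of 7. Without line 213 the preset adjusted p was 0.427 for the yolk and eggshell list and 0.0550 for muscle, and without both line 213 and line 38 it was 0.000172 and 0.0737. Leaving out line 38 alone gave 0.0561 for muscle. Leaving out line 213, alone or with line 38, also brought the antimicrobial list under 0.05. Leaving out both lines brought the Turandot list to a preset camera adjusted p of 0.0432 as well. None of the 5 calls held with an estimated correlation, where their adjusted p was between 0.316 and 0.853.

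**Figure D2:**
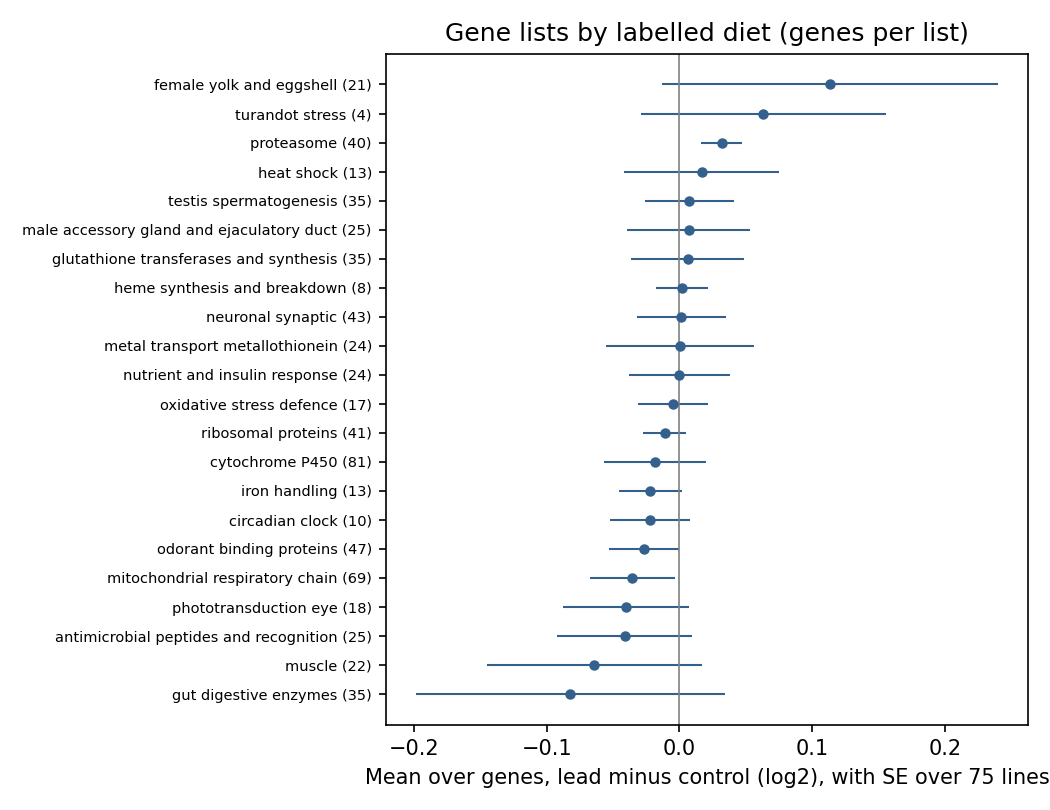
Mean lead minus control difference in log2 signal for each of the 22 gene lists by labelled diet, with the standard error over 75 lines as bars and the number of genes in parentheses. The yolk and eggshell list lies at 0.11 ± 0.13, or 0.0437 ± 0.107 without line 213, and the proteasome list at 0.0319 ± 0.0153.

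The second question was how far expression followed the inbred line on both diets. The line effect passed the threshold in 2 probe sets, egh, a glycosyltransferase gene, and CG32198. Control and lead values over the 75 lines correlated at r = 0.49 for egh and r = 0.53 for CG32198, both with an adjusted p of 0.0305 in limma's F-test, while 14 of 100 pairings gave as many calls. Both calls were lost with median centred arrays (adjusted p = 0.0513 for each) and without the 8 lines of lowest array correlation (0.204 for egh and 0.148 for CG32198). In lines 1 to 100 egh had an adjusted p of 0.181, and in lines above 200 neither passed, with r = -0.17 for CG32198. The other probe set of egh gave r = 0.064 (unadjusted p = 0.252), so the call rested on a single probe set of the gene. CG32198 had an SD of 0.99 on the arrays labelled control and 0.60 on those labelled lead. At an unadjusted p under 0.05 there were 2317 probe sets, or 12.3%, against a median of 716 when arrays of different lines were paired at random.

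Over all probe sets the median correlation between the diets was 0.0565, with a 5th percentile of -0.149 and a 95th percentile of 0.243. Metallothioneins gave r = 0.14 for MtnB, r = 0.19 for MtnD, r = 0.16 for MtnC and r = -0.014 for MtnA. Whole arrays of a labelled line were barely more alike than arrays of different lines, with mean correlations of 0.0668 and 0.000471 after removing the diet means (permutation p = 0.0218, 2-sided). A control array found its most similar lead array in its own labelled line in 1 of 75 cases, where chance gives 1.

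**Figure D3:**
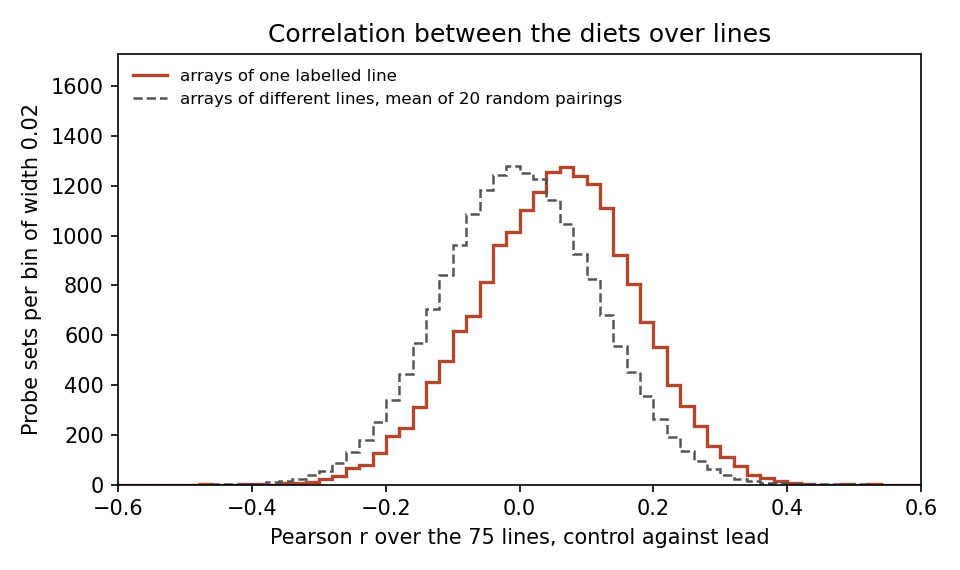
Distribution over 18769 probe sets of the Pearson correlation between control and lead values over the 75 lines, in bins of width 0.02, for the labelled lines (solid) and for the mean of 20 random pairings of different lines (dashed). The median of the labelled lines is 0.0565.

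The third question was whether lines varied more on lead food than on control food. The Pitman-Morgan test called 218 probe sets, 150 with a wider and 68 with a narrower spread on the arrays labelled lead, and the test on ranks called 0. Swapping the diet labels within lines gave at least as many calls in 65 of 100 splits, the real one included. The majority of wider calls did not hold in every alternative given below. At an unadjusted p under 0.05 there were 2163. Of the 21 yolk and eggshell genes, 6 were called, all with a wider spread. Genes are named by their probe set of highest mean. The log2 variance ratio was 3.73 for Cp19 and 3.57 for Cp16, both chorion proteins, 3.24 for Femcoat and 3.05 for Cp7Fc, and Cp18 and Vm32E were also called. Jig (3.42) and l(1)G0196 (3.32) completed the named genes with a wider spread. Among the narrower ones galene had -3.12, the cytochrome P450 Cyp303a1 -3.10, the testis gene janB -3.06, the glutathione transferase GstO1 -2.72, sdt -2.68 and Tengl4 -2.47. Among the other lists, Cyp310a1 and the zinc transporter gene Zip42C.2 had a narrower spread, and no other list had a call. Of the 4 other probe sets of l(1)G0196, 3 were called, with ratios of 4.44 (adjusted p = 1.61e-26, a larger ratio than that of Cp19), 2.60 and 1.28, and the remaining ratio was 0.55. The named probe set and those at 4.44 and 2.60 lay farthest from their medians on the same 2 arrays. These were labelled line 9 lead and line 78 lead, and without these lines the ratio of the named probe set was -0.25. The most variable of the other probe sets of sdt had SDs of 0.254 and 0.257 on the arrays labelled control and lead.

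Many of these calls were lost when the arrays farthest from a probe set's median were left out. In Cp19 the array labelled line 213 lead lay 5.97 above the median of 3.27 and the array labelled line 38 control 1.29 above it, while the third farthest array was 0.51 away. Without line 213 the log2 variance ratio of Cp19 was -0.53, that of Cp16 -1.06 and that of Femcoat -0.25. GstO1 deviated from its median by -3.27 on the array labelled line 50 control and by -2.94 on the array labelled line 89 control, with the next at -0.57. Without these 2 lines its ratio was -0.10. Similarly janB deviated by -6.59 and -6.28 on the arrays labelled line 58 control and line 15 control, and Tengl4 by -5.05 and -4.56 on those labelled line 81 control and line 226 control. Leaving out the line of the farthest array left 45 of the 218 probe sets under the largest p of a call, 0.00057, in the same direction, and leaving out the lines of the 2 farthest arrays left 11. Cp7Fc was among the 11 at a ratio of 1.75. Its 2 farthest arrays lay 3.26 and 2.91 above its median, and the third, which stayed in, lay 2.75 above it. Jig had a ratio of -0.38 without line 54, whose array labelled lead lay 4.31 above its median. These lines were chosen by the values themselves.

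The last comparison set the 18 lines numbered above 200 against the 57 lines numbered 1 to 100. In limma 0 probe sets differed in level and 0 in the response to labelled diet. At an unadjusted p under 0.05 there were 683 and 383. The smallest adjusted p was 0.202 for level and 1.00 for response, and the median standard errors were 0.0428 and 0.0806. No gene, MtnB and the other metallothioneins included, was named by this comparison.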

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

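The alternative without the lines with arrays high in eggshell genes, and the list means without single lines, were chosen after the result was seen. The count of probe sets between the labelled diets was 0 in all 12 alternatives run, including 0 with no replicate block, so the pairing changed no call. All of them use the same labels, so their agreement does not test whether the labels belong to the values. The pseudocount alternatives were not run because the values are logs, and the surrogate variables are not reported because their tool was not usable with these values. Under alternatives the 214 values of named diet genes never passed, and 22 of them changed sign. Gene lists passed only with the preset correlation of 0.01, which called 5. The line effect fell from 2 probe sets to 1 (egh) above the median of mean signal, 1 (CG32198) in lines 1 to 100, and 0 with median centred arrays, without the 8 lines of lowest array correlation and in lines above 200; r stayed between 0.43 and 0.50 for egh in all alternatives, and between 0.52 and 0.76 for CG32198 except in lines above 200 (-0.17). With median centring both had an adjusted p of 0.0513. Spread calls fell from 218 to 47 above the median of mean signal, 92 without the 8 lines of lowest array correlation (39 wider), 110 in lines 1 to 100 (45 wider), 121 without the lines high in eggshell genes (62 wider) and 0 on ranks, and rose to 332 in lines above 200 (314 wider). Log2 variance ratios reversed without the 8 lines in Cp19 (-0.92), Cp16 (-1.13) and Femcoat (-0.32), in lines 1 to 100 in the same genes (-0.69, -1.47 and -0.50, with Cp16 past the threshold in the opposite direction at an adjusted p of 0.0304), without the lines high in eggshell genes in Cp16 (-0.31), and in lines above 200 in Cyp303a1 (0.43) and janB (0.44); those alternatives leave out arrays on which the ratios rest. Calls were also lost, with smaller ratios, in lines 1 to 100 for galene (-0.20), in lines above 200 for Jig (0.20), l(1)G0196 (0.63), sdt (-0.36) and GstO1 (-1.09), and without the lines high in eggshell genes for Cp19 (0.76) and Femcoat (0.44). For the line number series, array weights called 1 probe set in level, which has no gene symbol; the cause was not tested, nor was that of the change with median centring or of the calls reached in lines above 200. All other results kept their counts within 1.5 times. Signal over background is not given per probe set, so dim probe sets could not be told from absent ones.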

Other observations

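The tests of matched arrays and of probe sets far from the rest on 2 arrays, and the relations between lists, were chosen after the result was seen, as were the alternatives without single lines. In several genes a split of the 150 arrays into 2 levels held most of the variance, whatever the labels. A rule on the share of variance between levels (over 0.8), with at least 20 arrays per level, picked 103 named genes, the metallothioneins MtnB and MtnD included. It asked for no gap between the levels. Cyp6a17, a cytochrome P450, had a low level with a median of 2.86 on 126 arrays and a high level of 8.48 on 24. Cyp6a20, the next gene with 2 levels in the gene order, also had 126 and 24 arrays, at 5.75 and 9.02. The peroxiredoxin Prx6c was at 5.47 on 118 arrays and 10.14 on 32, Map205 at 2.97 on 21 and 9.31 on 129, and CG10177 at 3.37 on 98 and 7.91 on 52. The chitinase-like Idgf6, the odorant binding protein Obp69a, GstD3 and RpL27 were also among them. The yolk and eggshell list held 3 genes with 2 levels, osk among them, where 0.181 are expected (Fisher's exact test, adjusted p over 22 lists 0.0161). That test treats genes as independent, while the diet differences of this list had an estimated correlation of 0.593, so its p may be too small. Vm26Aa, also among the 3, was high on 20 arrays, the fewest the rule allows.

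Gene lists varied together over the 150 arrays. Respiratory chain and muscle means correlated at r = 0.87 (rho = 0.89), and P450 and digestive enzyme means at r = 0.83 (rho = 0.85). Digestive enzyme and neuronal means correlated at r = -0.79 (rho = -0.78). In each case the permutation p of r and of rho was 1e-05, the smallest the resamples can give, and the adjusted p was 2.84e-05 for r and 2.88e-05 for rho. Without the 2 arrays farthest from the median, r was 0.90, 0.81 and -0.77, and all 3 relations held within each labelled diet. Of 253 relations computed, 152 passed. The permutations treat the 150 arrays as independent, though each line has 2, so these p-values and this count may overstate the evidence. The 3' minus 5' difference of Act5C, a sign of RNA quality, correlated with 18 of the 22 lists, at r = -0.76 (rho = -0.79) for the P450s and r = 0.69 (rho = 0.73) for the testis genes. Its r was -0.12 with muscle (rho = -0.07, adjusted p of r 0.217) and -0.27 with the respiratory chain (rho = -0.19), too weak for this measure to account for their r of 0.87. The relations of the digestive enzymes were not separated from it. Yolk and eggshell means were 8.87 on the array labelled line 213 lead and 7.57 on the array labelled line 38 control, against a median of 3.64 and 5.87 on the highest other array.

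Neighbouring genes with 2 levels varied together. MtnB and MtnD were left out here, which left 101 genes. The median absolute correlation of adjacent 2-level genes on a chromosome arm was 0.647 over 96 pairs, against 0.0904 on different arms. It was 0.241 for genes 2 to 10 places apart and 0.124 beyond, and the position permutation p was 1e-05, the smallest the resamples can give. Linked alleles segregating among the lines could give this, as a hypothesis, since genotypes were not used here. An absolute correlation above 0.8 was found in 25 adjacent pairs, but also in 17 of 3853 pairs on different arms. Linkage would not give pairs on different chromosomes, but pairs on the 2 arms of a chromosome were not set apart here. The adjacent pairs include CG43090 and the yolk gene Yp1, at r = 0.744. What sets the levels of the yolk and eggshell genes was not tested. Neighbours that share a probe sequence or a regulator stay open for single pairs such as Cyp6a17 and Cyp6a20.

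Arrays of a labelled line were barely more alike than others, although arrays had close partners. Over the 127 probe sets with 2 levels, metallothioneins left out, the median correlation of an array with its best match was 0.796. With its second best match the median was 0.538. The highest median best match in 100 shuffles was 0.241. The shuffles moved each probe set separately and so broke the correlation of neighbouring genes. They therefore set too low a baseline to decide alone whether lines differed too little in expression. The 2-array probe sets given below fell on matched arrays in 21 of 24 cases, where random reassignment gave at most 8. For the arrays they cover, that argues against too little difference. Of 65 pairs of arrays that were each other's best match (up to 46 arise after shuffling), 0 carried the same line number, where chance gives 0.436, and no constant shift of the titles along the columns gave more than 3. By label, 16 of the pairs were both control, 14 both lead and 35 one of each. The matched arrays lay on opposite sides of the gap in MtnB in 61 of 65 pairs, where random pairings gave at most 51. A batch unrelated to MtnB would leave it free to differ, as in the random pairings, whose median was 33. The 61 opposite pairs lie above their highest count and so argue against such a batch. Still open is a batch that itself set the 2 arrays of a pair apart in MtnB. The arrays labelled line 213 lead and line 38 control, both high in eggshell genes, were each other's best match. The source of that shared trait was not tested. A candidate explanation is that the values and labels of the table do not belong together, so that matched arrays may be a line on its 2 diets. The comparisons by labelled diet and by labelled line would then not measure lead or line. Their counts and intervals would not bound a response to lead, in the metallothioneins and heme genes included. Whether a mix-up arose in the deposit or in later handling stays open. So do a partial mix-up, a batch that also set MtnB apart and the weak excess of own-line correlation. No array was assigned to another label.

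A second set of genes bears on the same point. In 24 probe sets exactly 2 arrays lay over 2 from the median in the same direction while the third farthest was within 1, 15 of them lower and 9 higher. These fell on 17 distinct pairs of arrays, since several probe sets shared a pair, as 3 of l(1)G0196 did. The 2 arrays were each other's best match by the 2-level genes in 21 of the 24 probe sets and 15 of the 17 pairs, where random reassignment gave at most 8 probe sets, which is what a rare allele carried by a line on both of its arrays would give, and this may be the source. They carried the same line number in 0 of 24, against the labels naming the line of each array. Examples are AnxB11, at -4.43 and -3.80 on the arrays labelled line 5 control and line 13 lead, GstO1, EbpII at -2.42 and -2.41, FucTD at -4.72 and -3.94, and RFeSP at 5.00 and 4.14 above its median. With limits of 0.75 and 0.85 on the share of variance, 18 and 23 of the 24 were matched. Those limits gave 55 and 67 matched pairs, of which 43 and 65 lay on opposite sides of the gap in MtnB and 0 carried the same line number.

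Each result was set against other splits of the arrays. Where the observed count was 0, every split had to reach it, so the split test decided nothing there. Swapping the diet labels within lines reached the 0 observed probe sets in 100 of 100 splits, with at most 2, and the 0 observed lists in 100 of 100, with at most 1. With the preset correlation, 84 of 100 splits gave at least the real 5 lists, up to 15. The 490 unadjusted probe sets were undercut or equalled in 19 of 100. For the spread, 65 of 100 splits gave at least the real 218 calls, up to 872, so chance could not be excluded, and since the test on ranks called 0, a few arrays far from the rest are a candidate cause. For the line effect, 14 of 100 pairings gave at least the real 2 calls, up to 81, so chance could not be excluded for the calls. The median r of 0.0565 was reached in 4 of 100 pairings and the 2317 probe sets at an unadjusted p under 0.05 in 5 of 100, the real pairing included, so a weak overall likeness within labelled lines lay near the edge of the random pairings. For the line number series, 100 of 100 splits reached the 0 observed in response, with at most 1, and 100 of 100 the 0 observed in level, with at most 691. The highest counts for the spread, the line effect and the level between series may come from a structure among the arrays that the labels do not name, which was not tested.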
